A study of Mus musculus with 12 samples.

How the data were processed

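Total RNA from 12 mouse hearts was hybridised to Illumina whole-genome bead arrays, 1 array per heart. The labels put the hearts in 5 groups: 2 adult wildtype, 1 embryonic day 14 (E14), 3 untreated MCM controls, 3 collected 72 h and 3 collected 1 week after induction. Induced mice carried the EpA960 and MCM transgenes, were 2 to 4 months old and received tamoxifen at 20 mg/kg, either once or on 5 days in a row; which schedule went with which time is not given in the sources used here. The labels call the MCM hearts untreated, so exposure to tamoxifen and expression of the repeat RNA cannot be told apart in these comparisons. All hearts carry the strain label FVB.

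Per the file headers, each array file held the mean bead signal of every probe, an intensity on a linear scale without normalization or background subtraction, and a detection score between 0 and 1. The scanner software is not given in the sources used here. The authors' deposited value table held 1 normalized intensity per probe and array. The authors also deposited the source of a program that maps the quantiles of each array onto those of a master array. That mapping was recomputed with 100 quantiles over all probes and adult wildtype replicate 1 as the master. It gave the table's values for 100% of probes on each array within a tolerance of 0.001, with a largest difference of 5e-05. Scale (linear), centring (none) and direction of that table are therefore known, and its column medians lay between 129.5 and 129.8.

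The array files and the value table number their probes differently. Each of the 45281 probes was linked to 1 row of the value table by an exact match of its 12 normalized values after rounding. Names came from the platform annotation that accompanied the value table: 34885 probes had 1 gene symbol, 18 had several and 10378 had none. Symbols were looked up by gene identifier in the RefSeq table of assembly GRCm38.p6, and 78 probes whose identifier had no match kept the annotation's symbol. No genome build is given for the probes, so no coordinates are printed and the RefSeq table served only for names and for which genes neighbour each other.

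The score was turned into a detection p as 1 minus the score. Background was corrected by the normal-exponential model with background mean and spread inferred from the detection p (nec in limma 3.58.1, R 4.3.3, offset 16), followed by quantile normalization and log2. Probes with detection p below 0.01 on every array of at least 1 group were kept, 18370 in all, of which 15659 were named. Each gene was represented by its kept probe with the highest mean over the 12 arrays, leaving 10169 genes. The number of arrays limits the precision: a single model over all 12 arrays had 7 residual degrees of freedom per gene. The E14 group is 1 array and was assumed to vary like the others.

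Groups were compared with limma (lmFit on group means, eBayes with an intensity trend), and Benjamini-Hochberg adjusted p below 0.05 over all genes counted as a change. All adjusted p values for genes are from this fit. A value after ± is the standard error of a log2 change, or the SD of log2 signal where marked. A gene none of whose probes passed detection on any array of a group has only a bound there. For it the fold is given as "at least", from the brighter group's mean against the mean of, per array, the higher of the gene's own value and the lowest normalized signal among detected probes. The same bound is given where the probe that stands for the gene was dark on every array of a group while another probe of the gene was detected, and the text says so. No fold is given where only 1 of 3 arrays of a group detected that probe. The files carry no flag for saturation, so folds of Myh6 and Lpl, whose brighter group lay near the highest normalized signal, are also given as "at least".

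Lists of genes were fixed before the data were examined: fetal cardiac genes, adult sarcomere genes, calcium handling, ion channels and gap junctions, fatty acid oxidation, respiratory chain and TCA cycle, glycolysis and glucose uptake, MEF2 factors and muscle genes with known MEF2 sites, RNA-binding proteins and the DMPK locus, miRNA biogenesis, extracellular matrix, cell cycle, macrophage and leukocyte markers, cytokines and acute inflammation, interferon response, integrated stress and heat shock response, p53 targets, circadian clock, and markers of endothelium, fibroblasts, smooth muscle and pericytes, atria, erythroid cells, adipocytes, fast skeletal muscle, T and B cells, lung epithelium and sex. The 26 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over lists within a comparison. With the estimated correlation no list passed in the comparisons of 72 h, 1 week or adult wildtype hearts, and 2 passed in each E14 comparison. Without 72 h replicate 2, 7 passed in each comparison of 1 week or E14 hearts and none at 72 h or in adult wildtype against MCM.

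Named genes followed a rule fixed at the same time: the 10 largest rises and 10 largest falls by fitted log2 change, which for dark probes is no rank of the true change, among called genes for 72 h, 1 week and E14 against MCM, 5 and 5 for the other comparisons, up to 4 called members per list with the smallest adjusted p, and always Mef2a, Mef2c, Mef2d, Mbnl1, Mbnl2, Celf1, Celf2, Nppa, Nppb, Myh6 and Myh7 where measured. Mef2a and Mef2d were not among the tested genes. The text prints a selection of the genes the rule gives.

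The fit was tested on simulated data for 10169 genes, of which 100 changed 2-fold and 100 changed 4-fold. Each gene varied independently of the others, with its fitted spread on every array, the E14 array included. The simulation therefore tests neither whether the E14 heart varies like the others nor the effect of an array far from its group. For 72 h against MCM the fit recovered 87% of 2-fold and 100% of 4-fold changes with 9 false calls. For E14 against MCM it recovered 57% and 96% with 4 false calls, and for adult wildtype against MCM 91% and 100% with 14 false calls.

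Alternatives covered the background correction, the authors' values, scaling by medians, the detection filter, the variance prior, array weights, the arrays in the fit, each array left out, the replicate number as a block, all probes of a gene, and a 1.5-fold minimum. The following 3 were added after the data were examined: Xist level as a covariate, adult wildtype in place of MCM as the control, and the list tests with an estimated correlation and without 72 h replicate 2 together. Leaving out that array as such was planned, and the comparison of its 72 h genes with those of all arrays and the simulation without it were added. A block for slide or scan date was planned but not run, since the files hold neither. Unnamed probes were counted separately. Figures were drawn with matplotlib 3.10.9.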

Results

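Gene expression was measured in 12 mouse hearts to ask which transcripts are over- or under-expressed in a heart model of myotonic dystrophy type 1 (DM1), the muscle disease caused by an expanded CTG repeat in DMPK. EpA960/MCM mice express RNA with expanded CUG repeats in heart muscle after tamoxifen, and MCM mice, which carry the tamoxifen-activated recombinase, served as controls. The groups were 3 induced hearts at 72 h, 3 at 1 week, 3 MCM hearts, 2 adult wildtype hearts and 1 wildtype heart from embryonic day 14 (E14). Between 14202 and 16774 of 45281 probes were detected per array, with 41 or 42 beads behind the median probe. The signal at the 1st percentile of probes, a measure of background, lay between 54.4 and 59.1 on the 6 arrays of induced hearts and between 63.0 and 76.2 on the other 6. Arrays of 1 group correlated across genes at 0.962 to 0.994. The sex of the animals is not given in the sources used here. Xist, the transcript of the inactive X chromosome, had log2 signals of 10.82 to 11.60 in 72 h replicates 1 and 2, MCM replicates 1 and 2 and the E14 heart, and of 4.94 to 5.07 in the others, including all 3 hearts at 1 week. The Y-linked Eif2s3y had 9.80 in MCM replicate 1, which thus carried both signals. Y-linked signals disagreed elsewhere too: Kdm5d had 7.44 in the E14 heart beside its Xist, and 7.75 and 7.65 in the adult wildtype hearts, where Eif2s3y was 5.72 and 5.55.

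At 72 h only a small set of genes differed from MCM hearts. Of 10169 genes, 18 rose and 9 fell, while 762 had an unadjusted p below 0.05. The rises included Cacna2d3, an auxiliary subunit of voltage-gated calcium channels, from 5.38 ± 0.01 to 10.51 ± 0.20 log2 signal (SD, n = 3 each; at least 12.6-fold, adjusted p = 7.07e-10), the kinase gene Ulk4 (at least 4.43-fold, adjusted p = 3.47e-08) and the protocadherin Pcdhb12 (at least 4.77-fold, adjusted p = 1.10e-06). Zfp36l2, which encodes an mRNA-binding protein, rose at least 3.80-fold, Taok2 at least 4.86-fold, Dmrtc1a at least 2.44-fold, Glra3 at least 2.04-fold and Arhgap8 at least 1.61-fold. The probes of Cacna2d3, Ulk4, Pcdhb12, Zfp36l2, Dmrtc1a, Glra3 and Arhgap8 were dark in every heart without induction. They may have bound the induced repeat transcript, so the rise of these genes themselves remains open, as described below. Atrip, a partner of the DNA damage kinase ATR, rose 8.05-fold (adjusted p = 6.68e-08), and Xirp2, a striated muscle actin-binding protein, rose 6.67-fold (adjusted p = 3.46e-05). Both other kept probes of Arhgap8 and the other kept probe of Xirp2 differed by at most 0.15 on the log2 scale.

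Among the falls at 72 h were S100a8 and S100a9, calcium-binding proteins of neutrophils, at 2.51-fold (adjusted p = 0.00908) and 2.35-fold (adjusted p = 0.00328). The mitochondrial malate dehydrogenase Mdh2 fell 2.03-fold (adjusted p = 0.0264), the dynein light chain Dynll2 3.17-fold (adjusted p = 0.0374) and the lectin Clec2d 2.47-fold (adjusted p = 0.00872). Cwc22 and Cdnf fell 1.98-fold and 1.96-fold, Tesmin at least 1.43-fold and Rbbp9 1.60-fold. Other kept probes of Cwc22 lay at -2.19 and 0.08 and of Rbbp9 at -0.92 and 0.10, so the probes of both genes disagreed. Set against the 2 adult wildtype hearts in place of MCM, 15 of the 18 genes were again higher and 5 of the 9 again lower. Xirp2 (log2 difference -0.68, adjusted p = 0.119) and Dynll2 (0.06, adjusted p = 0.930) did not differ from adult wildtype. Neither did Clec2d (-0.19, adjusted p = 0.628) and Cwc22 (0.08, adjusted p = 0.730), and Rbbp9 was higher by 0.51 (adjusted p = 0.0445). Dynll2, Clec2d, Cwc22 and Rbbp9 were themselves lower in adult wildtype than in MCM (log2 differences -1.73, -1.11, -1.07 and -1.19). That control, chosen after the data were examined, called 766 genes at 72 h, 391 higher and 375 lower.

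The genes always reported did not pass at 72 h: log2 differences were 0.00 ± 0.12 for Mbnl1 and 0.01 ± 0.10 for Mbnl2, splicing regulators bound by CUG repeats, 0.00 ± 0.08 for Celf1, -0.12 ± 0.11 for Celf2 and -0.01 ± 0.11 for the transcription factor Mef2c. Natriuretic peptide B (Nppb) lay 0.84 ± 0.44 above MCM, with log2 signals of 13.99, 15.73 and 13.23 in replicates 1, 2 and 3 against 13.48 ± 0.04 (SD, n = 3) in MCM. Nppa and Myh7 lay 0.07 ± 0.44 and 0.51 ± 0.28 above MCM and Myh6 at -0.11 ± 0.10. As lists, fatty acid oxidation (median log2 change -0.29, adjusted p = 1.20e-08, adjusted p = 0.591 with an estimated correlation) and respiratory chain and TCA cycle genes (-0.12, adjusted p = 8.47e-05, adjusted p = 0.591 with an estimated correlation) were low under camera. Extracellular matrix (0.40, adjusted p = 8.47e-05), cell cycle (0.36, adjusted p = 4.87e-06) and macrophage and leukocyte markers (0.39, adjusted p = 0.000257) were high, each with adjusted p = 0.591 with an estimated correlation. In these 5 lists the single called gene was Mdh2, and the count adjusted over the list alone was also 1. Without 72 h replicate 2, none of the 5 lists passed (adjusted p between 0.0551 and 0.865) and cytokines and acute inflammation were low (median -0.25, adjusted p = 4.09e-06, adjusted p = 0.490 with an estimated correlation). The count of 27 genes became 54 without 72 h replicate 3, 561 with array weights and 10 among genes detected on all 12 arrays.

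**Figure D1:**
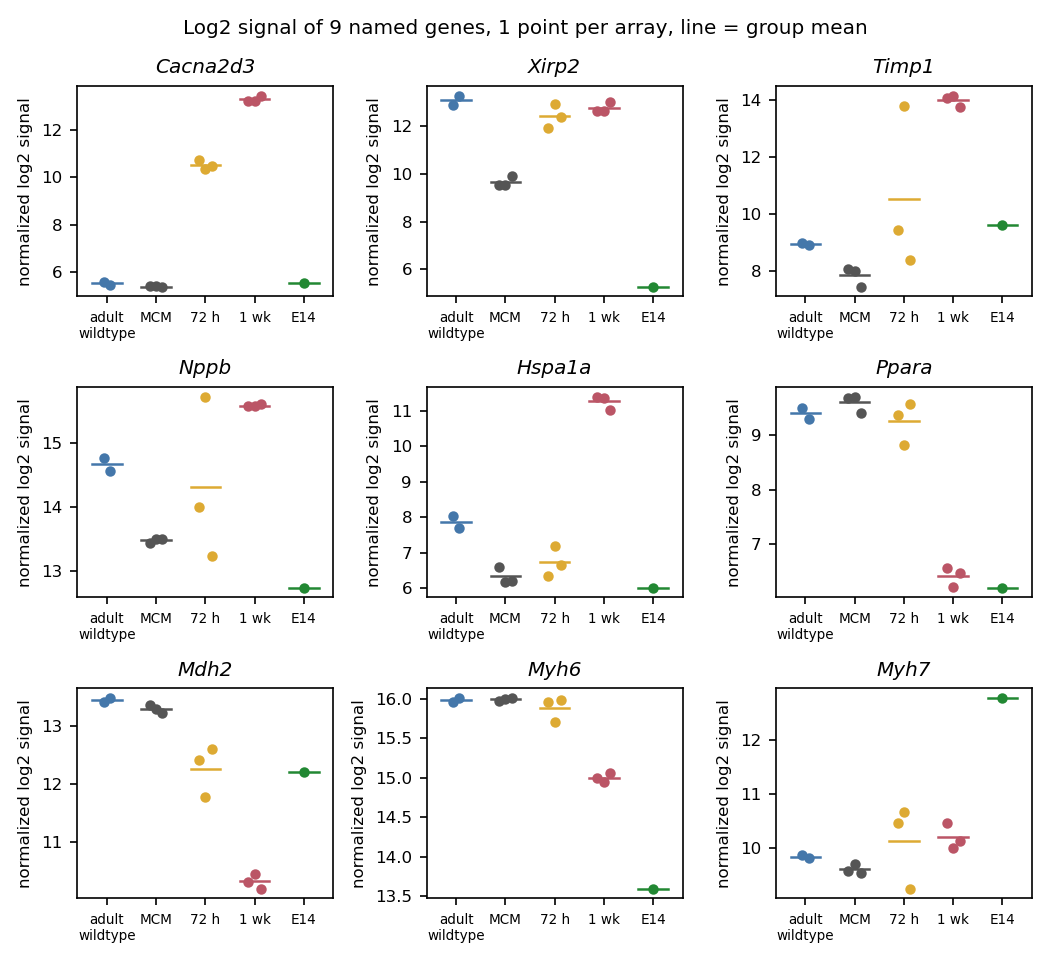
Normalized log2 signal (vertical axes, each with its own range) of 9 named genes in 5 groups of hearts, with 1 point per array and a line at the group mean. Cacna2d3 was at most 5.55 in all 6 hearts without induction, 10.51 on average at 72 h and 13.32 at 1 week, while Timp1 and Nppb in 72 h replicate 2 (13.76 and 15.73) lay far above the other 72 h hearts.

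One week after induction the heart transcriptome had changed broadly, with lower expression of genes for mitochondrial energy metabolism, ion channels and calcium handling and higher expression of genes for extracellular matrix, macrophages, cytokines and cellular stress. As lists these passed with the preset correlation, and none of the 11 called lists passed with an estimated one. Of 10169 genes, 2767 rose and 2709 fell against MCM, and 3638 changed by at least 1.5-fold. The rises again included Cacna2d3 (log2 signal 13.32 ± 0.12, SD, n = 3; at least 88.7-fold, adjusted p = 4.16e-12) and Ulk4 (at least 50.6-fold, adjusted p = 2.07e-11). Among the others were Sspn, which encodes the dystrophin-associated protein sarcospan (at least 42.5-fold, adjusted p = 6.38e-11), and Crct1 (at least 38.7-fold, adjusted p = 3.04e-10). Both of these were below detection on all arrays outside the 1 week group. Pcdhb12 and Zfp36l2 rose at least 25.0-fold and at least 23.6-fold. For Cacna2d3, Ulk4, Pcdhb12 and Zfp36l2 the rise of the genes themselves remains open, since their probes may have bound the induced repeat transcript. Timp1, an inhibitor of matrix metalloproteinases, rose 70.6-fold (log2 change 6.14 ± 0.97, adjusted p = 0.000282). The alternative-activation macrophage genes Chil3, Arg1 and Chil4 rose at least 20.9-fold, at least 18.4-fold and at least 25.6-fold.

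The falls at 1 week included Kcnv2, a silent potassium channel subunit (at least 5.51-fold, adjusted p = 1.35e-05), Ppara, the nuclear receptor that drives fatty acid oxidation genes (at least 7.50-fold, adjusted p = 3.59e-07), and Gpr22 (8.40-fold, adjusted p = 3.32e-06). Mdh2 fell 7.80-fold (adjusted p = 2.90e-07), the muscle gene Ky 7.55-fold, the mitochondrially encoded complex I subunit ND6 7.36-fold and Lrtm1 6.94-fold. Kitl fell at least 2.96-fold and the mitochondrial ribosomal protein gene Mrpl45 at least 2.93-fold. Syne2, a nuclear envelope protein linked to the cytoskeleton, fell at least 4.46-fold by a probe that was not detected at 1 week. The log2 changes of its 3 other kept probes were -2.16, -0.81 and 0.49, so its probes disagreed.

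Fatty acid oxidation genes fell together at 1 week: 20 of 27 fell and none rose (0 up and 21 down adjusted over the list alone; median log2 change -0.88, adjusted p = 5.65e-07, adjusted p = 0.446 with an estimated correlation). Beside Ppara, its coactivator Ppargc1a fell 3.51-fold, Etfdh 2.77-fold and Ech1 1.97-fold. In the respiratory chain and TCA cycle 33 of 37 genes fell, also 33 adjusted over the list alone (median -0.55, adjusted p = 3.59e-08, adjusted p = 0.417 with an estimated correlation), including cytochrome c (Cycs, 2.13-fold), Ogdh (2.34-fold) and Fh1 (2.17-fold). Glycolysis and glucose uptake genes went both ways, 4 up and 10 down, the same counts adjusted over the list alone (adjusted p = 0.156). Pfkfb2 and the muscle enolase Eno3 fell 2.90-fold and 2.86-fold, and Eno1b rose at least 2.21-fold.

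Most called genes of the ion channel, calcium handling and sarcomere lists fell at 1 week. Of 18 ion channel and gap junction genes 15 fell and 1 rose (1 up and 16 down adjusted over the list alone; median -1.18, adjusted p = 7.88e-06, adjusted p = 0.408 with an estimated correlation). Kcnk3, a background potassium channel, fell 4.46-fold, the ATP-sensitive potassium channel subunits Kcnj8 and Abcc9 fell 2.62-fold and 2.73-fold. In calcium handling 12 of 17 fell (13 adjusted over the list alone; median -0.73, adjusted p = 0.000189, adjusted p = 0.178 with an estimated correlation), with Jph2 down 2.40-fold, Cacnb2 2.73-fold and phospholamban (Pln) 2.83-fold. Asph fell 3.55-fold, but its probe among those detected on all 12 arrays changed by 0.15. Of 18 adult sarcomere genes 9 fell, also 9 adjusted over the list alone (median -0.41, adjusted p = 0.00136, adjusted p = 0.110 with an estimated correlation). Titin (Ttn) fell 2.19-fold, Ldb3 2.98-fold, Nexn at least 2.13-fold and Myh6, the adult alpha myosin heavy chain, at least 1.99-fold (adjusted p = 1.39e-05), with MCM signals of 15.97 to 16.02 near the top of the scale.

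The list of MEF2 factors and muscle genes with MEF2 sites had 10 of 19 genes lower and 3 higher, the same counts adjusted over the list alone (median -0.64, adjusted p = 0.0367, adjusted p = 0.332 with an estimated correlation). Ppargc1a, creatine kinase Ckm (2.55-fold) and Lmod3 (2.65-fold) fell, Xirp2 rose 8.52-fold against MCM but did not differ from adult wildtype (log2 difference -0.33, adjusted p = 0.285), and Mef2c itself fell 1.56-fold (log2 change -0.64 ± 0.11, adjusted p = 0.000625). Among RNA-binding proteins and genes of the DMPK locus 3 rose and 5 fell of 18, the same adjusted over the list alone (adjusted p = 0.256). The splicing factor Rbfox1 fell 3.72-fold, Hnrnph1 1.63-fold, Six5 2.37-fold and Dmpk 1.62-fold (adjusted p = 0.000182). Dmpk did not differ from adult wildtype at 1 week (log2 difference -0.04, adjusted p = 0.777). Mbnl1 (-0.12 ± 0.12), Mbnl2 (-0.21 ± 0.10), Celf1 (-0.07 ± 0.08) and Celf2 (0.14 ± 0.11) did not pass. Of 12 miRNA biogenesis genes 1 rose and 5 fell, the same adjusted over the list alone (adjusted p = 0.256), with Dicer1 and Drosha down 1.65-fold and 1.54-fold.

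Fetal cardiac genes were not called as a list (adjusted p = 0.156), and 3 of 11 rose, also 3 adjusted over the list alone. These were the matricellular growth factor gene Ccn2 (5.57-fold), smooth muscle actin Acta2 (2.40-fold) and Nppb (4.31-fold, adjusted p = 0.00175; 0.92 above adult wildtype, adjusted p = 0.141). Myh7, the beta myosin heavy chain of the fetal ventricle, lay 0.59 ± 0.28 above MCM (adjusted p = 0.0941) and Nppa 0.55 ± 0.44 above it. Without MCM replicate 3 the Nppa difference was -0.06: its log2 signal was 14.23 there and 16.04 and 16.07 in MCM replicates 1 and 2. These and its signals at 1 week (15.98 to 16.02) lie at the top of the scale, so a small difference does not show that Nppa was unchanged. The same array was low in the atrial genes Myl7 (9.08 against 13.53 and 14.23) and Sln (8.62 against 13.35 and 13.89), as was 72 h replicate 3 (10.83 and 10.54). Atrial markers were 0 up and 2 down of 9, the same adjusted over the list alone (adjusted p = 0.499), with Kcnj3 (detected on 2 of the 3 arrays at 1 week) and Gja5 down 2.15-fold and 2.32-fold.

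Extracellular matrix genes rose at 1 week, 25 of 30, the same adjusted over the list alone (median 1.37, adjusted p = 1.14e-06, adjusted p = 0.446 with an estimated correlation). Lox, which crosslinks collagen, rose (adjusted p = 0.000124, detected on 1 of 3 MCM arrays), Mmp14 rose 5.60-fold, Mmp2 2.07-fold and thrombospondin 1 (Thbs1) at least 3.26-fold. All 20 macrophage and leukocyte markers rose, also 20 adjusted over the list alone (median 1.89, adjusted p = 4.88e-08, adjusted p = 0.417 with an estimated correlation). Lgals3 rose 29.1-fold, Cd14 17.2-fold, Ctss at least 4.64-fold and the Fc receptor chain Fcer1g at least 4.56-fold. Of 20 cytokine and acute inflammation genes 17 rose and 1 fell, the same adjusted over the list alone (median 2.02, adjusted p = 1.89e-05, adjusted p = 0.446 with an estimated correlation). Serpina3n rose 24.0-fold, Ptx3 at least 6.03-fold and S100a9, which had fallen at 72 h, 2.31-fold. Beside these lists, fibroblast markers were 5 up and 1 down of 11, the same adjusted over the list alone (adjusted p = 0.151), with Mfap5 at 5.08-fold, and T and B cell markers 2 up of 5, also 2 adjusted over the list alone (adjusted p = 0.165). These counts include Tbx18 and Cd3e, whose probes were detected on no array at 1 week or in MCM and were kept through the E14 heart. Their calls thus compare signals below detection.

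Stress genes rose as well. In the integrated stress and heat shock list 20 of 25 rose and 2 fell (22 up and 2 down adjusted over the list alone; median 1.44, adjusted p = 7.32e-08, adjusted p = 0.110 with an estimated correlation). The heat shock protein Hspa1a rose at least 21.2-fold, asparagine synthetase Asns 11.6-fold, Chac1 6.20-fold and the transcription factor Atf3 at least 2.91-fold. The cell cycle list had 13 of 31 genes up and 2 down, the same adjusted over the list alone (median 0.48, adjusted p = 0.0347, adjusted p = 0.569 with an estimated correlation). Plk1 and Rrm2 rose at least 1.93-fold and at least 1.55-fold, and Ccnd2 and Cenpa fell 2.17-fold and 1.69-fold. Among p53 targets 6 rose and 1 fell of 13, the same adjusted over the list alone (adjusted p = 0.151), with the cyclin-dependent kinase inhibitor Cdkn1a up 9.60-fold and the apoptosis gene Bbc3, detected on 2 of 3 MCM arrays, 2.90-fold. Interferon response genes were 7 up and 1 down of 15, the same adjusted over the list alone (adjusted p = 0.238).

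Single genes among the markers of other cell types and the circadian clock changed at 1 week, but none of these lists passed. Erythroid genes were 4 up and 1 down of 9 (5 up and 1 down adjusted over the list alone; adjusted p = 0.153), with the heme synthesis gene Alas2 up 7.93-fold. Smooth muscle and pericyte markers were 2 up and 5 down of 10 (3 up and 6 down adjusted over the list alone; adjusted p = 0.256), endothelial markers 3 up and 4 down of 13, the same adjusted over the list alone (adjusted p = 0.967). Adipocyte markers were 3 up of 5, also 3 adjusted over the list alone (adjusted p = 0.284), and fast skeletal muscle markers 2 down of 8 (1 adjusted over the list alone; adjusted p = 0.329). Of 12 circadian clock genes 3 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.808): Arntl rose at least 3.28-fold, Dbp and Per3 fell 2.91-fold and at least 3.17-fold. Lung epithelium markers had 3 tested genes, too few for a list test, and none was called (Ager adjusted p = 0.0519, Cldn18 0.0925, Sftpc 0.213). None was detected in MCM, and at 1 week only Ager was, on 2 of 3 arrays. With adult wildtype hearts in place of MCM, 2031 of the 2767 higher and 1982 of the 2709 lower genes were called in the same direction and 49 in the opposite one. Arntl (log2 difference 0.34, adjusted p = 0.175), Alas2 (0.80, adjusted p = 0.0583) and Kcnj3 (-0.70, adjusted p = 0.0644) did not pass against adult wildtype. Of the 3 called adipocyte markers, Car3 (-0.26, adjusted p = 0.677) and Adipoq (-0.23, adjusted p = 0.648) did not pass there either. The third, Ucp1, was lower than in adult wildtype (-1.57, adjusted p = 0.0011). Its probe was detected on 1 of 3 arrays at 1 week and on none in MCM. With an estimated correlation and without 72 h replicate 2, a combination chosen after the data were examined, 7 lists passed at 1 week: ion channels (adjusted p = 0.0352), adult sarcomere, calcium handling, respiratory chain and TCA cycle, macrophage markers and stress genes (adjusted p = 0.0486 each) and cytokines (adjusted p = 0.0495). The -R suffix that the labels give all 3 arrays at 1 week is not explained in the sources used here, and no other group shares it.

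**Figure D2:**
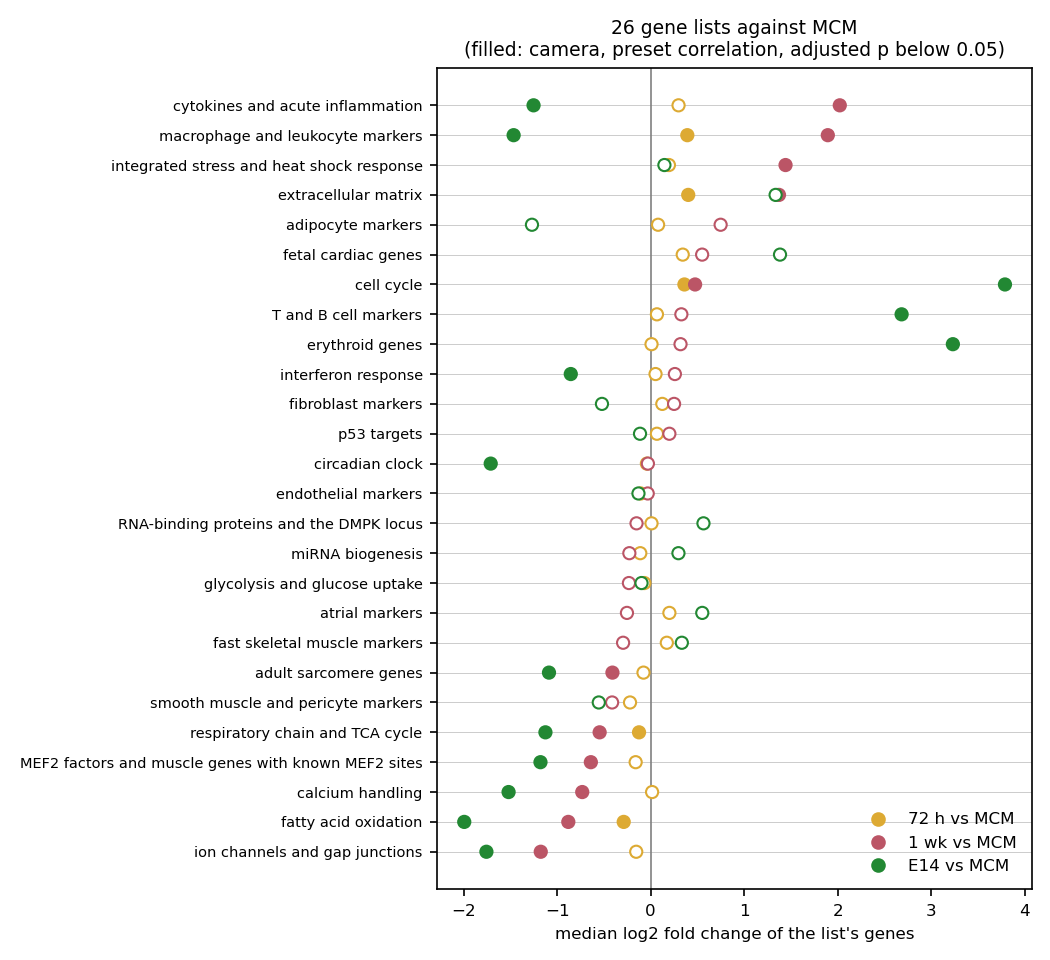
Median log2 fold change against MCM (horizontal axis) of 26 gene lists at 72 h, at 1 week and in the E14 heart. Filled points passed camera with the preset correlation. Ion channels and fatty acid oxidation were lowest at 1 week (-1.18 and -0.88) and cytokines highest (2.02), and the cell cycle list was highest in the E14 heart (3.79).

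The difference between the times was tested directly: 2350 genes were higher and 2266 lower at 1 week than at 72 h. Sspn (at least 41.6-fold) and Crct1 (at least 37.8-fold) were among the rises, as were Chil3, Chil4 and the myeloid lectin Clec4d (adjusted p = 0.000165, 9.94e-05 and 1.60e-05). Of the 72 h arrays only replicate 2 detected these 3 genes (log2 signals 8.67, 8.77 and 7.67), so no fold is given. The falls included Gpr22 (6.24-fold), ND6 (6.10-fold), Ppara (at least 5.89-fold), Syne2 (at least 3.48-fold by a probe not detected at 1 week) and Kitl (at least 2.45-fold). S100a8 and S100a9 were 6.82-fold and 5.42-fold higher at 1 week, and Ager, detected on 2 of 3 arrays there and on none at 72 h, was called higher (adjusted p = 0.0375). Of 26 lists 10 were called: down were ion channels (14 of 18), calcium handling (11 of 17), respiratory chain and TCA cycle (25 of 37), fatty acid oxidation (16 of 27, 1 up), adult sarcomere (10 of 18) and MEF2 genes (10 of 19, 2 up). Up were macrophage markers (19 of 20), extracellular matrix (17 of 30), cytokines (16 of 20, 1 down) and stress genes (19 of 25, 1 down). Adjusted over the list alone, the counts of these lists were 14, 14, 26, 19, 11, 10, 20, 22, 17 and 20. With an estimated correlation their adjusted p lay between 0.102 and 0.602, and 7 lists passed without 72 h replicate 2 (adjusted p between 0.0219 and 0.0356).

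**Figure D3:**
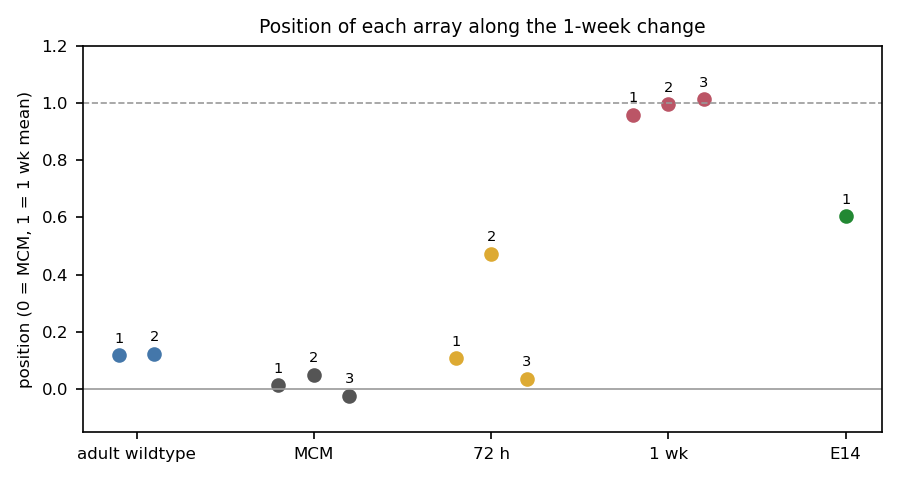
Position of each array along the change from MCM (0) to the 1 week hearts (1) over the genes called at 1 week, with the replicate number above each point and arrays that define the axis left out in turn. 72 h replicate 2 sat at 0.473, replicates 1 and 3 at 0.108 and 0.037, the adult wildtype hearts at 0.119 and 0.124 and the E14 heart at 0.605.

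The E14 heart differed from MCM in genes of the cell cycle, embryonic globins and slow troponin, which were higher, and in genes of energy metabolism, the adult sarcomere and the circadian clock, which were lower. Of these lists only adult sarcomere and circadian clock passed with an estimated correlation too. Of 10169 genes 3291 were higher and 2928 lower. The embryonic globins Hbb-y (log2 signal 16.06 in the 1 E14 array, below detection in MCM; at least 589-fold, adjusted p = 8.61e-12) and Hba-x (at least 176-fold) were among the higher genes, as were the imprinted genes Dlk1 (at least 185-fold) and Mest (adjusted p = 5.74e-10, detected on 1 of 3 MCM arrays) and the slow troponin Tnni1 (at least 90.9-fold). Bex4, Capn6 and the histone gene H2ac22 were at least 46.2-fold, at least 37.9-fold and 84.5-fold higher, and Cdk1 and Top2a at least 31.7-fold and at least 24.9-fold. Among the lower genes were Rpl3l, the striated muscle form of a ribosomal protein (at least 318-fold), Rbp7 (at least 68.5-fold), the lipid droplet genes Plin4 and Plin5 (at least 57.4-fold and at least 52.9-fold), Tuba8 (at least 77.9-fold) and the mitochondrial creatine kinase Ckmt2 (137-fold). Lrtm1 was 119-fold lower, and 2310002L09Rik, Ly6c1 and Lrrc2 were at least 79.3-fold, at least 79.9-fold and at least 30.9-fold lower. Other kept probes differed in size. On the log2 scale they lay at 1.46 and 4.40 for Top2a, 1.67 and 7.64 for Bex4, -4.34 for Plin5, -1.87 for 2310002L09Rik and -1.23 and -6.15 for Tuba8.

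All 31 cell cycle genes were higher at E14, also 31 adjusted over the list alone (median 3.79, adjusted p = 1.99e-11, adjusted p = 0.249 with an estimated correlation), with Cdk4 at 6.29-fold and Rrm1 at 7.06-fold. Erythroid genes were 7 up of 9 (8 adjusted over the list alone; adjusted p = 0.000115, adjusted p = 0.194 with an estimated correlation). Fatty acid oxidation was 26 down of 27, also 26 adjusted over the list alone (median -1.99, adjusted p = 2.74e-09, adjusted p = 0.379 with an estimated correlation), with Ech1 12.6-fold and Lpl at least 5.99-fold lower. The respiratory chain and TCA cycle were 34 down and 1 up of 37, the same adjusted over the list alone (adjusted p = 5.48e-10, adjusted p = 0.379 with an estimated correlation), with Cox8b 7.01-fold lower. Adult sarcomere genes (14 down, 1 up of 18, the same adjusted over the list alone) and circadian clock genes (11 down, 1 up of 12, the same adjusted over the list alone) passed with an estimated correlation as well, with adjusted p = 0.0468 and adjusted p = 0.04996. Tcap was 19.4-fold, Myom2 25.6-fold and Dbp 19.6-fold lower. Ion channels were 14 down and 3 up of 18 (adjusted p = 0.000574, adjusted p = 0.379 with an estimated correlation), with Scn4b at least 23.7-fold lower by a probe not detected at E14, and calcium handling 11 down and 1 up of 17 (adjusted p = 0.000253, adjusted p = 0.139 with an estimated correlation), with Hrc 10.7-fold lower. Adjusted over the list alone these counts were the same.

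MEF2 genes were 12 down and 1 up of 19 at E14 (adjusted p = 0.00122, adjusted p = 0.0957 with an estimated correlation), with Slc2a4 16.6-fold lower. Macrophage markers (12 down of 20, adjusted p = 0.00233, adjusted p = 0.646 with an estimated correlation), cytokines (11 down, 2 up of 20, adjusted p = 0.0322, adjusted p = 0.655 with an estimated correlation) and interferon genes (11 down of 15, adjusted p = 0.00647, adjusted p = 0.379 with an estimated correlation) were low. T and B cell markers were 4 up of 5 (adjusted p = 0.0232, adjusted p = 0.379 with an estimated correlation), with Cd3g at least 6.47-fold higher. Adjusted over the list alone these counts were the same, except 1 T and B cell gene lower. The lung epithelium markers Cldn18 and Sftpc were detected in the E14 heart and on no MCM array, and were called higher (adjusted p = 4.16e-05 and 4.57e-05). Myh6 was at least 5.28-fold lower and Myh7 8.93-fold higher, Mbnl1 and Mbnl2 were 2.03-fold and 2.15-fold lower (adjusted p = 0.000309 and 4.17e-05), and Celf1 lay 0.27 ± 0.12 above MCM (adjusted p = 0.0686). Dmpk was 7.49-fold lower. Without 72 h replicate 2, 7 lists passed with an estimated correlation (adjusted p between 0.0319 and 0.0410). With a single embryonic heart these differences have no replicate check, and the median log2 change of all genes was 0.07, against 0.26 when scaled by medians, with 3868 genes then higher and 2431 lower.

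Against the 2 adult wildtype hearts the E14 heart had 3090 genes higher and 2745 lower. Hbb-y (at least 580-fold), Hba-x (at least 173-fold), Dlk1 (at least 182-fold), Tnni1 (at least 89.5-fold) and Capn6 (at least 37.4-fold) were among the higher genes, and Rpl3l (at least 296-fold), Xirp2 (at least 102-fold), 2310002L09Rik (at least 116-fold), Plin4 (at least 54.5-fold) and Ckmt2 (131-fold) among the lower. As against MCM, the balance of higher and lower genes depends on the scaling. The median log2 change of all genes was 0.06, against 0.25 when scaled by medians. The other kept probe of 2310002L09Rik lay at -0.88 on the log2 scale and that of Xirp2 at -3.26. Mbnl1 and Mbnl2 were 2.29-fold and 1.97-fold lower, and Nppb 3.82-fold lower (adjusted p = 0.0244). Of 26 lists 15 were called, and adult sarcomere and circadian clock genes passed with an estimated correlation too (adjusted p = 0.0403 for both). Without 72 h replicate 2, 7 passed (adjusted p between 0.0295 and 0.0296). Adipocyte markers were 5 down of 5, also 5 adjusted over the list alone (adjusted p = 0.00592, adjusted p = 0.122 with an estimated correlation), and endothelial markers 7 down of 13, also 7 adjusted over the list alone (adjusted p = 0.0198, adjusted p = 0.122 with an estimated correlation). Cldn18, Sftpc and Ager, detected on no adult wildtype array, were called higher too (adjusted p = 2.37e-05, 3.03e-05 and 0.0426). Hbb-bh1 was at least 13.9-fold higher, but without the detection filter another of its probes stood for it, at -0.83.

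Adult wildtype and MCM hearts differed: 266 genes were higher and 316 lower in adult wildtype. With scaling by medians these counts were 194 and 308. The induced hearts also carry MCM. Of the 50 called genes that differed over 4-fold, all but Xirp2 had 72 h means nearer to MCM than to adult wildtype. At both times this held for 32, but the 1 week hearts had changed broadly. Other features that the MCM and 72 h hearts may share were not tested. These differences are thus not shown to come from the transgenic line itself. Several differences were near all-or-none. Lrrc2 had log2 signals of 11.35 ± 0.06 (SD, n = 3) in MCM and 5.04 ± 0.06 (SD, n = 2) in adult wildtype, at least 22.3-fold lower (adjusted p = 1.67e-10). Rbp7 was at least 49.4-fold, Pdrg1 at least 13.0-fold, the protease gene Ctsc at least 6.95-fold and Lrrc57 at least 5.14-fold lower. Xirp2 was 10.7-fold higher in adult wildtype (adjusted p = 5.52e-06), with 9.66 ± 0.22 (SD, n = 3) in MCM against 13.08 ± 0.27 (SD, n = 2), while its other kept probe differed by 0.32. Dctn1 was 6.41-fold, the platelet gene Tubb1 at least 2.39-fold and the clock gene Arntl at least 2.60-fold higher, as was the platelet gene Ppbp (adjusted p = 0.00908, detected on 1 of 3 MCM arrays).

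Among the lists, adipocyte markers were 3 up of 5 in adult wildtype, also 3 adjusted over the list alone (adjusted p = 0.0114, adjusted p = 0.398 with an estimated correlation), with the brown fat uncoupling protein Ucp1 at least 1.69-fold and Car3, detected on 2 of 3 MCM arrays, 4.44-fold higher. Erythroid genes were 4 up of 9, also 4 adjusted over the list alone (adjusted p = 0.0114, adjusted p = 0.485 with an estimated correlation), with Alas2 at 4.56-fold. Fast skeletal muscle markers were 2 down of 8 (4 adjusted over the list alone; adjusted p = 0.00933, adjusted p = 0.485 with an estimated correlation) and interferon response genes 3 down of 15 (1 up and 4 down adjusted over the list alone; adjusted p = 0.0344, adjusted p = 0.850 with an estimated correlation). Clock genes went both ways, 3 up and 4 down of 12 (4 up and 5 down adjusted over the list alone; adjusted p = 0.474), with Per2 3.42-fold and Dbp 1.97-fold lower. Dmpk was 1.57-fold lower in adult wildtype (adjusted p = 0.00579), while Myh6, Myh7, Mbnl1, Mbnl2, Celf1, Celf2, Mef2c, Nppa and Nppb did not pass. The count of 582 genes became 187 or 201 without adult wildtype replicate 1 or 2, 316 or 343 without MCM replicate 1 or 2, 1308 without 72 h replicate 2, 1116 with the compared arrays alone, 2146 with array weights and 373 among genes detected on all 12 arrays.

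The changes after induction were then set against the embryonic-adult difference, which shares no array with them. Across 10169 genes, which are not independent replicates, the E14 against adult wildtype change correlated with the 1 week change at r = 0.290 (Spearman rho = 0.331). Both comparisons called 1143 genes higher and 1329 lower, where independent lists of these sizes would share 840.8 and 731.3. Opposite calls numbered 409 and 413, where 746.9 and 823.2 would be shared. Of the 200 genes highest in E14, 111 rose and 6 fell at 1 week (median log2 change 0.68, adjusted p = 7.82e-09, adjusted p = 0.210 with an estimated correlation). Of the 200 lowest, 121 fell and 25 rose (median -0.69, adjusted p = 7.82e-09, adjusted p = 0.210 with an estimated correlation). At 72 h the correlation was r = 0.296 (rho = 0.326), but 0.064 without 72 h replicate 2 and 0.153 with array weights. The 72 h and 1 week changes correlated with each other at r = 0.633 (rho = 0.580), at 0.264 without 72 h replicate 2 and at 0.358 with array weights. Simulated unchanged groups sharing the 3 MCM arrays gave a mean of 0.4997 and at most 0.545 over 100 simulations. Genes were simulated as independent, so this range leaves out variation that genes of an array share. The observed correlation had a standard error of 0.344, from a jackknife that left out each array but E14 in turn. Its excess over the simulated values is therefore not established. The simulated groups were also unchanged, while 5476 genes were called at 1 week. Such changes lower the correlation that shared controls alone would give. The simulated correlations are thus no reference for the observed one in either direction. The covariance was 0.139 against 0.0171 simulated. Without 72 h replicate 2 the simulated mean correlation was 0.445, which is no reference for 0.264 for the same reason. The covariance was then 0.0487 against a simulated mean of 0.0169 and at most 0.0191.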

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

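The results in this paragraph met a rule for a closer look. The difference between the times was tested directly and held for 4616 genes, 2350 higher and 2266 lower at 1 week than at 72 h. Probes without a gene name, which the comparisons of genes do not use, changed as well: 1396 at 1 week and 5 at 72 h against MCM.

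A set of 11 probes, among them Cacna2d3, Adam15, Ulk4, Pcdhb12 and Zfp36l2, was dark in all 6 hearts without induction and lit in all 6 induced hearts, with median log2 changes of 3.25 at 72 h and 5.88 at 1 week. Hybridisation of the induced repeat transcript to these probes predicts that other probes of the same genes stay unchanged, and 17 other probes of 7 of these genes had a median log2 change of 0.1211 at 1 week (0.396 for the 5 detected in all induced hearts), which is consistent with it, although probes that work poorly would stay dark too. A part in the general response at 1 week predicts higher levels in 72 h replicate 2, which had moved furthest along that response, and it lay at -0.4203 against replicates 1 and 3, which differed by -0.0626, but 1 heart cannot exclude that part. The sequences of the transgene and of the probes are not analysed here, so the rise of these genes themselves remains open. Both tests were written after the data were examined.

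72 h replicate 2 stood at 0.473 along the change from MCM to 1 week, far from the other 72 h hearts. A 1 week heart labelled as 72 h predicts full levels of the 11 induced-only probes, but they lay at -2.438 against the 1 week mean (SD of the 1 week arrays 0.1407). Sex predicts the same position for replicate 1, which shares high Xist, but it stood at 0.108. A poor array without direction predicts no relation to the 1 week change, and the deviation of replicate 2 correlated with it at 0.62, but its position was measured along that same change, so the test decides nothing and a poor array remains open. So does a heart further along the response, which was not tested, and the first 2 tests were written after the data were examined.

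Adult wildtype and MCM hearts differed in 582 genes although all carry the same strain label. Sequence variants under single probes predict that other probes of a called gene do not differ, and over 136 genes their median difference was 0.6007 of that of the called probes, which leaves variants under some probes open. As the source of all calls they were not supported, since other probes lay on the same side for 83.09% of genes (95% CI 75.71 to 88.97), a test written after the data were examined. Segments of another strain predict called genes next to each other, and 47 neighbouring pairs against a permuted median of 33 (p = 0.0069 over 10000 permutations) are consistent with such segments. The ratio was 1.42 here and between 0.9997 and 1.03 in the 1 week and E14 comparisons. Those called 4604 to 6207 of 10149 placed genes, against 578 here, and so many calls hold the ratio near 1. They therefore do not show how far called genes lie together without such segments.

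With 3 hearts in each group there are only 10 splits of the 6 arrays, too few for a share under 0.05. In each comparison 1 split, the real one, reached the real count: 27 genes at 72 h against at most 15 for another split, 5476 at 1 week against 0, and 4616 between the times against 0.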

How the results depend on the processing

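The groups, lists, naming rule and most alternatives were chosen before the data were examined; the Xist covariate, adult wildtype as the control and an estimated correlation combined with leaving out 72 h replicate 2 were chosen after. Of 509 called gene results, 447 kept direction and call under every alternative run for single genes, which leaves out the covariate, the other control, the fit of only the arrays compared, the fold minimum and the use of any probe. Of 58 list calls, 40 kept theirs in every setting with the preset correlation and 4 with an estimated correlation. Where no cause is given, the cause was not tested.

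For 72 h against MCM the count of 27 became 10 among the 7242 genes detected on all 12 arrays, 561 with array weights, 15 with only the arrays compared and 766 with adult wildtype in place of MCM. For adult wildtype against MCM, 582 became 373, 2146 and 1116 under the first 3 of these. A minimum of 1.5-fold left 3638 genes at 1 week and 2883 between the times, which its construction makes fewer. The correlation of the E14 and 1 week changes, 0.2904, became 0.3123 without background correction, 0.3171 with the authors' values and 0.3708 among genes detected on all 12 arrays.

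Leaving out 1 array at a time gave 18 to 54 genes for 72 h, 4642 to 6078 for 1 week, 3681 to 5603 between the times, 5801 to 6748 for E14 against MCM, 5056 to 6449 for E14 against adult wildtype and 187 to 1308 for adult wildtype against MCM. The correlations ranged from 0.06381 to 0.3511 for E14 with 72 h, 0.2787 to 0.2963 for E14 with 1 week and 0.2639 to 0.6716 for 72 h with 1 week. The median of the macrophage list at 72 h turned to -0.03282 without 72 h replicate 2 and reached 0.665 without replicate 3. Without 72 h replicate 2 the 72 h count was 37, with 26 of the 27 genes shared. Groups left with 1 array were assumed to vary like the others. The single E14 heart could not be left out of its own comparisons, so their ranges hold none of its variation.

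Without a detection filter another probe stood for Celf4 (-0.01036 in E14 against MCM) and Hbb-bh1 (-0.4577 against MCM, -0.8278 against adult wildtype), and among genes detected on all 12 arrays for Asph at 1 week (0.1504). With the replicate number as a replicate block the counts were 34 for 72 h, 5479 for 1 week, 4645 between the times and 495 for adult wildtype against MCM. After each group's mean was subtracted per gene, samples sharing a number correlated at -0.04173 to 0.3066. Not every one correlated best with its own number, so the numbers were not taken as pairs. With the Xist covariate the counts were 40, 5628, 4683 and 608. A block for slide or scan date was not run, since the files hold neither. Detection limits depth: 31.4% to 37.0% of probes passed per array.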

Other observations

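Single genes of the circadian clock differed between groups whose time of collection is not given in the sources used here. Log2 signals of Arntl were 5.59 in MCM, 6.03 at 72 h, 8.57 at 1 week and 8.23 in adult wildtype, and Dbp was 2.91-fold lower at 1 week and 1.97-fold lower in adult wildtype than in MCM. Against MCM, the globin gene Hbb-b2 was 2.33-fold higher at 1 week and 4.18-fold higher in adult wildtype.

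Probes of called genes did not always agree. Other kept probes lay on the same side for 8 of 11 genes at 72 h, 1847 of 2164 at 1 week and 168 of 202 in adult wildtype against MCM. Apart from the 11 induced-only probes, 4 probes were lost in all induced hearts and 179 were lit at 1 week alone.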
